A study of Mus musculus with 15 samples.

How the data were processed

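The data were single-colour expression arrays of mouse liver, 1 array per animal, with intensity values as deposited by the authors. Per the labels' protocols total RNA was isolated with a mirVana kit, 300 ng went into the Affymetrix WT synthesis and amplification kit, and biotin-labelled cDNA was hybridized. Male mice aged 7.5 months received DEHP in corn oil, or corn oil alone, by gavage for 4 days. The nulls and the wild-type mice came from different 129 substrains, so substrain and genotype cannot be told apart. The deposited values were positive and linear, from 1.77 to 23336.67, with near-equal medians and quartiles in all arrays, so they had already been brought to a common scale. The method of that normalization, the scanner settings and the assignment of animals to batches are not given in the sources used here.

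Log2 was taken of every value and no further normalization was applied. Of 35494 probe sets 21789 had 1 gene symbol, 1621 several and 12084 none in the annotation used here, and 21698 were matched to a gene identifier. Of the 999 genes with several probe sets the one with the highest mean was kept, which left 19938 genes. No 2 arrays were identical. Genes without a probe set of their own symbol were not analysed here.

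A linear model with 1 mean per group was fitted to all 15 arrays in limma, with moderated t tests (residual degrees of freedom 11, prior 4.68). The contrasts were DEHP against corn oil in wild-type and in null mice, the difference of these differences, and null against wild type in controls and under DEHP. P values were adjusted by Benjamini and Hochberg over all genes of a contrast, with a threshold of 0.05 and no minimum fold. Adjusted p of genes come from limma and those of lists from camera. Standard errors are the moderated ones of limma.

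The 42 gene lists covered PPARα targets (peroxisomal, mitochondrial, other), CAR, PXR, NRF2 and aryl hydrocarbon receptor targets, cholesterol synthesis, lipogenesis, bile acids, glucose, urea and amino acids, acute phase, complement and coagulation, stress responses, proteasome, cell cycle, p53, interferon, clock, sex-biased genes, oxidative phosphorylation, lysosome, lipoproteins, iron, matrix, and markers of liver and other cell types. They were written from textbook knowledge before the files were opened. Each was tested with camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, which asks whether the genes of a list move at all, while camera asks whether they move more than other genes. Called members were also counted with p adjusted over the list alone. Some genes stand in several lists. Named genes were the 3 receptors, the largest rises and falls in which the groups did not overlap, up to 4 called members per list, and fixed markers. The result for a gene or list was recomputed without each animal.

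Chance was judged by relabelling the animals of a contrast in all 35 splits, or in 100 drawn splits for the interaction. The drawn splits relabelled animals within each genotype, with wild-type animal WT-56 kept in the DEHP group. In a self-test on simulated data each gene kept its mean and residual SD, with independent normal noise, and chosen genes were raised or lowered. Of 100 moved 1.5-fold, 93 were recovered in the wild-type and 82 in the null contrast, and of 100 moved 2-fold 98 and 100. Among all genes called in it, 7.7% (16 of 207) and 5.7% (11 of 193) had not been moved, and 0 of 42 lists were called. Genes of real data move together, which this test did not cover. The number of arrays limits the precision of every estimate. The work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.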

Results

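Liver mRNA was measured on 15 arrays, each from a separate male mouse: 4 wild-type mice given corn oil, 4 wild-type mice given di(2-ethylhexyl) phthalate (DEHP) at 1150 mg/kg/day for 4 days, 4 PPARα-null mice given corn oil and 3 PPARα-null mice given DEHP. PPARα is the nuclear receptor of fatty acids and of peroxisome proliferators such as DEHP. The title of the series names the activation of PPARα and of the constitutive androstane receptor CAR as its subject. Of 35494 probe sets, those with a single gene symbol gave 19938 genes. Over all 35494 probe sets, median intensity per array ran from 44.4 to 47.5. Arrays of the same group correlated at r = 0.988 to 0.992 across these probe sets, which are not independent replicates. The first 3 principal components of their log2 values held 17.2, 10.4 and 9.7% of the variance. Animals carry the number of their label after KO (null) or WT (wild type). Gene lists, the rule for named genes and the main tests were fixed before the data were examined, and tests added after a result was seen are marked as such. Differences are given as log2 values ± standard error from limma, with p adjusted over all genes, and a gene is said to have risen, fallen or changed only where the adjusted p was below 0.05.

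The receptor genes came first. Ppara, which encodes PPARα, had a mean log2 intensity of 9.78 ± 0.12 (SD, n = 4) in wild-type controls and 9.09 ± 0.11 (n = 4) in null controls, a difference of -0.69 ± 0.12 (fold 0.619, adjusted p = 0.00645). Under DEHP the same difference was -0.64 ± 0.13 (adjusted p = 0.00422, n = 4 wild-type and 3 null). The single probe set for the gene thus still read a mean intensity of 545 in null controls, against 881 in wild-type controls, and which part of the gene it covers is not given in the sources used here. DEHP left Ppara at 0.03 (adjusted p = 0.935) in wild-type mice. Nr1i3, which encodes CAR, read 0.08 (adjusted p = 0.724) after DEHP in wild-type mice and 0.31 ± 0.09 (adjusted p = 0.124) in null over wild-type controls. Nr1i2, which encodes the pregnane X receptor PXR, read 0.16 (adjusted p = 0.295) after DEHP in wild-type mice.

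In wild-type livers the largest rises with DEHP were in ω-hydroxylases, acute phase proteins and enzymes of lipid metabolism (n = 4 against 4). The cytochrome Cyp4a14, which ω-hydroxylates fatty acids, rose 31.3-fold (4.97 ± 0.44, adjusted p = 9.76e-06), and its relatives Cyp4a31 and Cyp4a10 rose 19.8-fold (4.30 ± 0.36) and 8.42-fold (3.07 ± 0.21, adjusted p = 7.2e-07). The acute phase proteins Saa2 and Saa1 rose 50.6-fold (5.66 ± 0.62, adjusted p = 9.3e-05) and 26.2-fold (4.71 ± 0.58), and Lcn2, an iron-siderophore binding protein, rose 14.1-fold (3.81 ± 0.59, adjusted p = 0.00155). Vnn1, a pantetheinase, rose 13.5-fold (3.75 ± 0.27), Mogat1, a monoacylglycerol acyltransferase, 7.76-fold (2.96 ± 0.17, adjusted p = 9.17e-08). Ehhadh, the bifunctional enzyme of peroxisomal β-oxidation, rose 7.58-fold (2.92 ± 0.15, adjusted p = 6.54e-08), and Acot1, an acyl-CoA thioesterase, 6.48-fold (2.69 ± 0.27). Among the largest falls were the adipokine gene Serpina12 (-1.65 ± 0.30, adjusted p = 0.00522), the G protein regulator Rgs16 (-1.62 ± 0.31), Lrtm1 (-1.41 ± 0.21) and the imprinted noncoding RNA Meg3 (-1.18 ± 0.19). They also held the organic anion transporter Slco1a4 (-1.15 ± 0.20), the liver pyruvate kinase Pklr (-1.05 ± 0.15) and Arrdc3 (-1.04 ± 0.21).

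DEHP changed 770 genes in wild-type mice, 456 up and 314 down, of which 55 moved at least 2-fold (46 up, 9 down). In 2367 genes (11.9%) no animal of one group fell within the range of the other, where chance gives 2.86%, and 748 of the 770 called genes were among them. The highest number called by any other of the 35 splits of these 8 animals was 1. The real split was thus 1 of 35, the lowest share this test can give. The count fell to 433, 472 and 473 without wild-type control WT-53, WT-54 or WT-55.

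**Figure D1:**
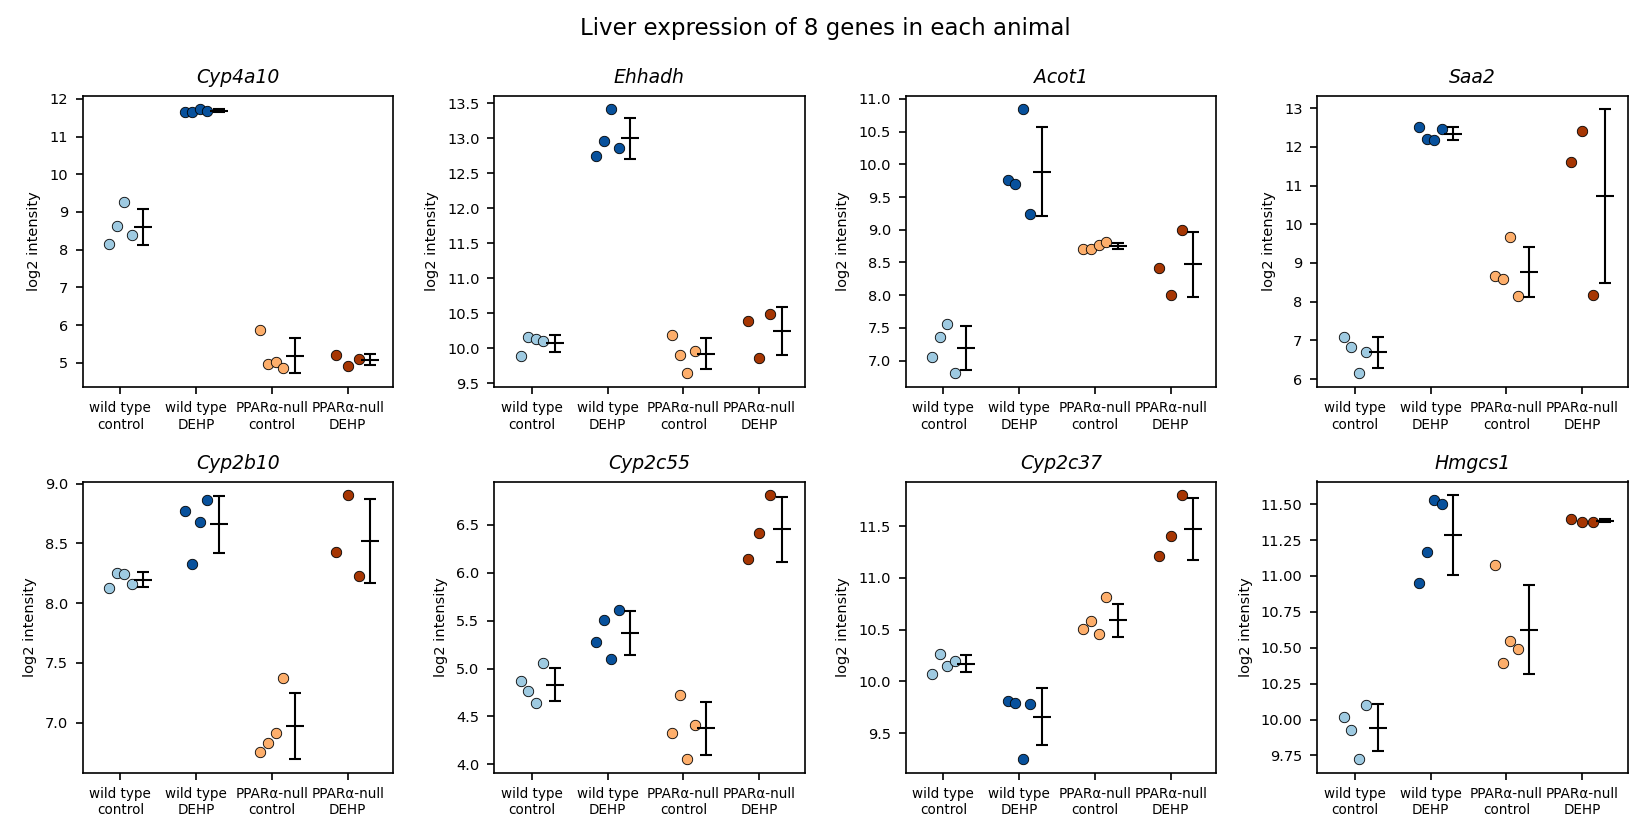
Log2 intensity of 8 genes in each animal of the 4 groups. Points are animals, bars are group means ± SD (n = 4, 4, 4 and 3).

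Of the 27 measured genes of peroxisomal fatty acid oxidation and peroxisome proliferation, 11 rose and 0 fell in wild-type mice, and 15 rose when adjusted over the list alone (median 0.36, camera adjusted p = 8.76e-14, adjusted p = 0.112 with an estimated correlation). Besides Ehhadh they included the peroxisomal thiolase Acaa1b (1.46 ± 0.15), the carnitine acetyltransferase Crat (1.13 ± 0.22) and the dienoyl-CoA isomerase Ech1 (0.96 ± 0.10). Of 23 mitochondrial fatty acid oxidation, carnitine shuttle and ketone body genes, 14 rose, 0 fell, and 18 rose when adjusted over the list alone (median 0.35, adjusted p = 2.04e-23, adjusted p = 0.0665 with an estimated correlation). Acot2, a mitochondrial acyl-CoA thioesterase, rose by 2.24 ± 0.28, Pdk4, which switches off pyruvate oxidation, by 1.11 ± 0.23, and the β-oxidation enzymes Eci1 and Decr1 by 1.01 ± 0.11 and 0.83. Of 31 other known PPARα targets 16 rose, 0 fell, and 20 rose when adjusted over the list alone (median 0.52, adjusted p = 3.18e-25). Among them the fatty acid transporter Cd36 rose 5.87-fold (2.55 ± 0.16, adjusted p = 1.86e-07), while the hepatokine Fgf21 read 0.13 (adjusted p = 0.801). DEHP animal WT-58 lay above the other DEHP animals. Its medians of the peroxisomal, mitochondrial and other lists were 0.744, 0.69 and 0.77 from the mean of all arrays. The other DEHP animals ran from 0.229 to 0.319, 0.353 to 0.369 and 0.326 to 0.459, and no wild-type control exceeded 0.101 in any of these lists.

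CAR targets went both ways in wild-type mice. Of 32 measured, 4 rose and 4 fell, with 6 up and 5 down when adjusted over the list alone (median 0.07, camera adjusted p = 0.239). The xenobiotic cytochromes Cyp2b10, the classic CAR target, and Cyp2c55 read 0.46 ± 0.15 (1.38-fold, adjusted p = 0.115) and 0.54 ± 0.16 (1.45-fold, adjusted p = 0.0715). The growth arrest gene Gadd45b rose by 0.66 ± 0.12 (adjusted p = 0.00414), while Meg3 (-1.18 ± 0.19) and the cytochromes Cyp2c37 and Cyp2c54 fell (-0.51 ± 0.14 and -0.52). Cyp2c37 (adjusted p = 0.0452) lost its call whichever of the 8 animals was left out, up to adjusted p = 0.115 without DEHP animal WT-58, and Cyp2c54 lost it in 5 of 8 cases, up to adjusted p = 0.0755. Cyp2b9 read 0.13 (adjusted p = 0.657) and the glutathione transferase Gstm3 0.14 (adjusted p = 0.607). Of 16 PXR targets 4 rose and 1 fell, 5 and 2 when adjusted over the list alone (median 0.055, and 0.016 to 0.103 with control WT-53 or DEHP animal WT-56 left out, adjusted p = 0.111). Cyp3a11, a drug-oxidizing cytochrome, rose 1.38-fold (0.46 ± 0.09, adjusted p = 0.00749), and the efflux pump Abcb1b rose by 0.82 ± 0.14 (adjusted p = 0.00405).

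Of 27 targets of NRF2, the transcription factor of the oxidative stress response, 10 rose and 2 fell in wild-type mice, 13 and 2 when adjusted over the list alone (median 0.16, camera adjusted p = 2.38e-08). The metal-binding metallothioneins Mt2 and Mt1 rose by 2.14 ± 0.44 and 1.44, the malic enzyme Me1 by 0.81 ± 0.14 and the quinone reductase Nqo1 by 0.56. Mt1 and Mt2 also stand in the acute phase list and Me1 in the lipogenesis list. Mt1 and Nqo1 lost their calls in 5 and 3 of 8 leave-out fits, up to adjusted p = 0.0896 and 0.0597, both without control WT-55. Of 7 aryl hydrocarbon receptor targets 1 rose and 1 fell, the same when adjusted over the list alone (median 0.007, and -0.052 to 0.058 with control WT-55 or DEHP animal WT-59 left out, adjusted p = 0.62), with Cyp1a1 at 0.04 (adjusted p = 0.911). With a correlation estimated from the data, camera still called the NRF2 targets, the other PPARα targets and the female-biased genes in wild-type mice (adjusted p = 0.0237 each), the CAR targets in null mice (adjusted p = 0.0345) and the other PPARα targets between genotypes under DEHP (adjusted p = 0.0489), and no list in the interaction or between the control groups.

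Of 20 cholesterol synthesis genes 12 rose and 0 fell in wild-type mice, with 17 up when adjusted over the list alone (median 0.54, camera adjusted p = 3.14e-22, adjusted p = 0.0792 with an estimated correlation). Hmgcs1, which makes the HMG-CoA for the pathway, rose 2.54-fold (1.34 ± 0.14, adjusted p = 7.9e-05), and the later enzymes Mvd, Pmvk and Cyp51 by 1.19 ± 0.16, 0.94 ± 0.14 and 0.88 ± 0.12. Of 24 bile acid genes 2 rose and 4 fell, 3 and 4 when adjusted over the list alone (median -0.12, adjusted p = 0.111). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 1.68 ± 0.41 (adjusted p = 0.0331), a call lost in 6 of 8 leave-out fits, up to adjusted p = 0.0979 without DEHP animal WT-56. Of 28 lipogenesis genes 5 rose and 2 fell, 6 and 5 when adjusted over the list alone (median 0.04, and -0.023 to 0.097 with DEHP animal WT-58 or control WT-52 left out, adjusted p = 0.276), with the acetyl-CoA carboxylase Acacb up by 1.35 ± 0.16. Of 18 glucose metabolism genes 4 fell, among them Pklr, the glucose transporter Slc2a2 (-0.67 ± 0.08), the glucose 6-phosphate transporter Slc37a4 (-0.66 ± 0.08) and the glycogen phosphorylase Pygl (-0.41 ± 0.06). None of that list rose, and 2 rose and 4 fell when adjusted over the list alone (median -0.017, and -0.048 to -0.003 with DEHP animal WT-58 or WT-57 left out, adjusted p = 0.0769).

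Of 26 acute phase genes 8 rose and 0 fell in wild-type mice, 10 and 1 when adjusted over the list alone (median 0.32, camera adjusted p = 1.64e-09, adjusted p = 0.206 with an estimated correlation). The plasma protein gene Orm2 rose by 1.94 ± 0.33 beside Saa1, Saa2 and Lcn2. Of 32 complement and coagulation genes 1 rose and 8 fell, 1 and 12 when adjusted over the list alone (median -0.14, adjusted p = 2.81e-06, adjusted p = 0.206 with an estimated correlation). Coagulation factor XI, F11, fell (-0.56 ± 0.10), as did factor V, F5 (-0.34 ± 0.07). Of 18 endothelial markers 5 fell and 0 rose, 10 down when adjusted over the list alone (median -0.23, adjusted p = 1.32e-06, adjusted p = 0.204 with an estimated correlation), with the sinusoidal scavenger receptor Stab2 at -0.33 ± 0.06 and Bmp2 at -0.43. Bmp2 lost its call in 7 of 8 leave-out fits, up to adjusted p = 0.104 without control WT-53. Of 30 proteasome subunits 5 rose and 0 fell, 11 up when adjusted over the list alone (median 0.15, adjusted p = 1.32e-11, adjusted p = 0.206 with an estimated correlation). Psma7, one of them, rose by 0.30 and lost its call in 2 of 8 leave-out fits, up to adjusted p = 0.0557 without DEHP animal WT-58.

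In PPARα-null livers the cytochromes Cyp2c55 and Cyp2b10 were among the largest rises with DEHP (n = 3 DEHP animals against 4 controls). Cyp2c55 rose 4.22-fold (2.08 ± 0.17, adjusted p = 3.86e-05), the classic CAR target Cyp2b10 2.93-fold (1.55 ± 0.16, adjusted p = 0.000635), and Cyp2c37 1.85-fold (0.88 ± 0.15, adjusted p = 0.0213). The acyl-CoA synthetase family gene Acsm2 rose 1.68-fold (0.75 ± 0.10, adjusted p = 0.0054) and the D-lactate dehydrogenase Ldhd 1.59-fold (0.67 ± 0.08, adjusted p = 0.00157), while Fabp2, a fatty acid binding protein, fell by 0.87 ± 0.11 on the log2 scale (adjusted p = 0.00412). Cyp4a10, Cyp4a14, Ehhadh and Acot1 read -0.10, 0.13, 0.32 and -0.28 (adjusted p = 0.912, 0.951, 0.463 and 0.783), and the mean intensity of Cyp4a14 was 46 in null controls and 42 in null DEHP mice, against 11020 in wild-type DEHP mice.

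DEHP changed 94 genes in null mice, 32 up and 62 down, of which 5 moved at least 2-fold (3 up, 2 down). All 94 had groups without overlap, as did 1991 genes (10%) in total where chance gives 5.71%. The highest number called by any other of the 35 splits of these 7 animals was 4, so that 1 of 35 called as many. The size of the count hung on single animals: it was 9 without DEHP animal KO-122, 19, 21 and 47 without control KO-117, KO-118 or KO-115, 34 without DEHP animal KO-123, and 168 without control KO-116. With only these 2 groups in the model it was 1.

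Of the 32 CAR targets 7 rose and 0 fell in null mice, and 14 rose when adjusted over the list alone (median 0.21, camera adjusted p = 1.86e-09). Besides the cytochromes named above, the carboxylesterase Ces2a rose by 0.82 ± 0.13 (adjusted p = 0.0213), and lost its call in 2 of 7 leave-out fits, up to adjusted p = 0.0885 without DEHP animal KO-122. Cyp2c37 lost its call in 3 of 7, with the same highest value, 0.0885, without the same animal. The median difference of the list from the mean of all arrays was 0.137, 0.251 and 0.199 in the 3 null DEHP animals and ran from -0.146 to 0.016 in the null controls. Of 16 PXR targets 3 rose and 0 fell, 7 up when adjusted over the list alone (median 0.08, adjusted p = 0.000311, adjusted p = 0.182 with an estimated correlation), and without control KO-117 the median was 0.053. The 3 that rose were Cyp3a44, Ces2a and Gstm1, and Ces2a and Gstm1 also stand in the CAR list. Cyp3a44, a cytochrome of the PXR list, rose by 0.89 ± 0.17 (adjusted p = 0.0351), a call lost in 5 of 7 leave-out fits, up to adjusted p = 0.172, while Cyp3a11 read 0.39 (adjusted p = 0.0826). Of 27 NRF2 targets 2 rose and 0 fell, 9 and 2 when adjusted over the list alone (median 0.14, adjusted p = 0.000294, adjusted p = 0.179 with an estimated correlation). Of these the glutathione transferase Gstm1 rose by 0.38 and lost its call in 5 of 7 leave-out fits, up to adjusted p = 0.112. Gstm1 thus counts in the CAR, PXR and NRF2 lists, so the calls of these lists are not independent.

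None of the 27 peroxisomal and none of the 23 mitochondrial fatty acid oxidation genes changed in null mice, with 0 peroxisomal genes and 1 mitochondrial gene, a fall, when adjusted over the list alone (medians 0.09 and 0.09, camera adjusted p = 0.396 and 0.359). Without DEHP animal KO-122 camera called the peroxisomal list (adjusted p = 0.0371, median 0.135). Of the 31 other PPARα targets 0 rose and 1, Fabp2, fell, 2 and 2 when adjusted over the list alone (median 0.03, and -0.026 to 0.109 with DEHP animal KO-121 or control KO-115 left out, adjusted p = 0.794).

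Of 20 cholesterol synthesis genes 2 rose and 0 fell in null mice, and 18 rose when adjusted over the list alone (median 0.46, camera adjusted p = 4.14e-15, adjusted p = 0.182 with an estimated correlation). Hmgcs1 rose 1.69-fold (0.76 ± 0.16, adjusted p = 0.0455) and the isoprenoid enzyme Idi1 by 0.64 ± 0.13 (adjusted p = 0.0405). Hmgcs1 lost its call in 6 of 7 leave-out fits, up to adjusted p = 0.181, and Idi1 in 5, up to 0.227, both without DEHP animal KO-122. Of 26 acute phase genes 2 rose and 0 fell, 13 and 1 when adjusted over the list alone (median 0.28, adjusted p = 8.39e-09, adjusted p = 0.326 with an estimated correlation). Without DEHP animal KO-122 its median was 0.171. Orm2 rose 3.36-fold (1.75 ± 0.36, adjusted p = 0.0442), and lost its call in 6 of 7 leave-out fits, up to adjusted p = 0.232. Saa2 read 1.96 ± 0.67 (adjusted p = 0.212), with log2 intensities of 11.60 and 12.42 in DEHP animals KO-121 and KO-122 and 8.17 in animal KO-123. None of the 32 complement and coagulation genes was called, and 9 rose when adjusted over the list alone (median 0.14, adjusted p = 1.25e-07, adjusted p = 0.283 with an estimated correlation).

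Of 36 oxidative phosphorylation genes none was called in null mice, and 1 rose and 15 fell when adjusted over the list alone (median -0.16, camera adjusted p = 9.13e-09, adjusted p = 0.413 with an estimated correlation), with Cox7a2, a subunit of cytochrome c oxidase, at -0.48 (adjusted p = 0.0654). Without DEHP animal KO-122 the median was -0.087. Of 30 proteasome subunits 0 rose and 1, Psma3 (-0.44, adjusted p = 0.0351), fell, 1 and 8 when adjusted over the list alone (median -0.13, adjusted p = 5.26e-08, adjusted p = 0.413 with an estimated correlation). Psma3 lost its call in 4 of 7 leave-out fits, up to adjusted p = 0.172. Over the 66 genes of both lists the medians of the null DEHP animals, -0.108, -0.233 and -0.104, overlapped those of the null controls, -0.015, -0.129, -0.026 and 0.061 (difference -0.121, exact two-sided permutation p = 0.114, a test added after the result was seen). The transcription regulators Id3 (-0.94 ± 0.18) and Id1 (-0.59), the lipid transporter Mfsd2a (-1.19 ± 0.25) and the chemokine Ccl3 (-1.07 ± 0.21) fell. Their calls were lost in 5, 7, 6 and 5 of 7 leave-out fits, up to adjusted p = 0.187, 0.172, 0.117 and 0.103.

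Camera called 5 more lists in null mice, nearly all of whose members stayed uncalled. None of 18 endothelial markers changed, and 2 rose and 1 fell when adjusted over the list alone (median 0.14, camera adjusted p = 0.00175, adjusted p = 0.435 with an estimated correlation). None of 24 bile acid genes changed, and 6 rose when adjusted over the list alone (median 0.11, adjusted p = 0.000296, adjusted p = 0.182 with an estimated correlation). Of 26 lysosome genes 1 rose, Lipa (0.38, adjusted p = 0.0329), 5 when adjusted over the list alone (median 0.10, adjusted p = 0.000348, adjusted p = 0.182 with an estimated correlation), and Lipa lost its call in 5 of 7 leave-out fits, up to adjusted p = 0.172. None of 21 matrix genes changed, and 1 fell when adjusted over the list alone (median -0.10, adjusted p = 0.00544, adjusted p = 0.62 with an estimated correlation). None of 14 B and plasma cell markers changed, and 0 when adjusted over the list alone (median -0.125, adjusted p = 0.00594, adjusted p = 0.524 with an estimated correlation). Leaving out 1 animal ended the matrix call (KO-123, adjusted p = 0.373, median -0.02) and the B cell call (KO-115, adjusted p = 0.0822, median -0.08), and without KO-122 the matrix median was -0.185.

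The response to DEHP differed between genotypes in 179 genes (interaction test, n = 15), 112 with the higher DEHP effect in wild-type mice and 67 with the lower. The DEHP effect is the log2 change from control to DEHP mice, so a lower effect need not mean a lower intensity. Of the genes named by the rule, those with the most positive difference, wild type minus null, included lipid enzymes and the pantetheinase Vnn1. The difference of differences was 4.84 ± 0.65 for Cyp4a14 (adjusted p = 0.00257), 3.71 ± 0.40 for Vnn1, 3.31 ± 0.25 for Mogat1 (adjusted p = 1.05e-05), 3.18 ± 0.32 for Cyp4a10 (adjusted p = 0.000157), 2.97 ± 0.40 for Acot1 and 2.60 ± 0.23 for Ehhadh (adjusted p = 4.84e-05). Among those with a lower DEHP effect in wild-type mice were 4 cytochromes, with a difference of -1.54 ± 0.23 for Cyp2c55 (adjusted p = 0.00604), -1.40 ± 0.20 for Cyp2c37 (adjusted p = 0.00422), -1.09 ± 0.22 for Cyp2b10 (adjusted p = 0.0308) and -1.04 for Cyp2c54 (adjusted p = 0.0163). For Cyp2c54 the wild-type change was -0.52 and the null change 0.52 (adjusted p = 0.0886). The call of Cyp2b10 was lost in 7 of 15 leave-out fits, up to adjusted p = 0.0778 without null DEHP animal KO-122. Saa2 read 3.70 ± 0.91 (adjusted p = 0.0675) and Cyp3a11 0.07 (adjusted p = 0.866).

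The 179 calls stood against 336 as the highest among 100 splits drawn with the group sizes kept, and 2 of the 100, the real one included, called at least as many. Relabelling within each genotype breaks up the DEHP effect itself. These splits thus stand for no DEHP effect at all, not for an equal effect in both genotypes, and cannot test the difference alone. In the split with 336 the null animals KO-116, KO-118, KO-121 and KO-122 were relabelled. The wild-type groups stayed as they are, which kept the wild-type DEHP effect whole, and why this split called more was not tested. Counted with a split and its mirror image kept apart, as first written, the drawing gave 1 of 100. The count was 299 without null control KO-116, 61 without wild-type control WT-53, 65 without null DEHP animal KO-122, 86 without null control KO-115, and at most 113 without any of wild-type control WT-52, WT-54 or WT-55, wild-type DEHP animal WT-56, null control KO-117 or null DEHP animal KO-123.

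Among mitochondrial fatty acid oxidation genes 7 of 23 had a higher DEHP effect in wild-type mice and 0 a lower, 12 when adjusted over the list alone (median 0.39, camera adjusted p = 3.91e-15, adjusted p = 0.135 with an estimated correlation). The same held for 4 of 27 peroxisomal genes, 7 when adjusted over the list alone (median 0.28, adjusted p = 5.66e-09, adjusted p = 0.178 with an estimated correlation), and 9 of 31 other PPARα targets, 15 when adjusted over the list alone (median 0.41, adjusted p = 2.05e-17, adjusted p = 0.135 with an estimated correlation). Of the 32 CAR targets 0 had a higher and 6 a lower DEHP effect in wild-type mice, 1 and 10 when adjusted over the list alone (median -0.11, adjusted p = 0.000107, adjusted p = 0.135 with an estimated correlation), and without null DEHP animal KO-121 the median was -0.22. None of the 20 cholesterol synthesis genes was called, and 0 when adjusted over the list alone (median 0.059, adjusted p = 0.0245, adjusted p = 0.64 with an estimated correlation). That call ended without any of 7 animals, up to adjusted p = 0.242 without null control KO-115, where the median was -0.019. Hmgcs1 read 0.59 (adjusted p = 0.221).

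Beyond the receptor targets, 5 of 30 proteasome subunits, among them Psma7 (0.61) and Psma3 (0.66), had the higher DEHP effect in wild-type mice, 14 when adjusted over the list alone (median 0.27, camera adjusted p = 4.62e-18, adjusted p = 0.135 with an estimated correlation). So had 3 of 36 oxidative phosphorylation genes, 17 when adjusted over the list alone (median 0.25, adjusted p = 4.37e-12, adjusted p = 0.208 with an estimated correlation). A lower DEHP effect in wild-type mice was found for 3 of 32 complement and coagulation genes, 18 when adjusted over the list alone (median -0.27, adjusted p = 2.14e-13, adjusted p = 0.135 with an estimated correlation), and for 2 of 18 endothelial markers, 13 when adjusted over the list alone (median -0.37, adjusted p = 3.38e-09, adjusted p = 0.135 with an estimated correlation). The effect in wild-type mice was lower by 0.81 on the log2 scale for Apoa4, an apolipoprotein (adjusted p = 0.000172). It was higher by 1.48 for Fabp2 (adjusted p = 0.000192) and by 1.80 for the adipocyte fatty acid binding protein Fabp4 (adjusted p = 0.00725). The endothelial gene Stab2 (-0.43, adjusted p = 0.0234) lost its call in 7 of 15 leave-out fits, up to adjusted p = 0.0718, and Pklr (-1.13, adjusted p = 0.0245) in 6, up to 0.0599.

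Of the 770 genes called in wild-type and the 94 called in null mice, 19 were shared: 15 rose in both (0.7 expected by chance from the 2 counts), 2 fell in both (1 expected), Fabp2 rose in wild-type and fell in null mice, and Cyp2c37 fell in wild-type and rose in null mice. The count of genes that rose in both hung on single animals and settings. It was 2 without KO-122, 3 without WT-54, 4 without KO-118 and 1 with only 2 groups in each model. It was 43 (3.22 expected) with a trended robust prior and 62 (10.2 expected) without the dimmer 50% of genes. Hmgcs1, Idi1, Orm2, Orm1, Cyp3a44 and the lysosomal lipase Lipa were among those that rose in both. In null mice these lost their calls in some leave-out fits, up to adjusted p = 0.181, 0.227, 0.232, 0.112, 0.172 and 0.172 in that order. In wild-type mice Cyp3a44 and Lipa did, up to adjusted p = 0.0652 and 0.131. Cyp2c37 did in both, up to adjusted p = 0.115 in wild-type and 0.0885 in null mice. Of the 770 genes 510 (66.2%) had the same sign in null mice, with a slope of 0.186 and a median ratio of 0.139, and 124 (16.1%) were called in the interaction. Of the 94 genes 52 (55.3%) had the same sign in wild-type mice, and 30 were called in the interaction. Across all genes, which are not independent replicates, the log2 changes of the genotypes correlated at r = 0.181 with a jackknife standard error of 0.081, and their rank correlation was 0.087.

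**Figure D2:**
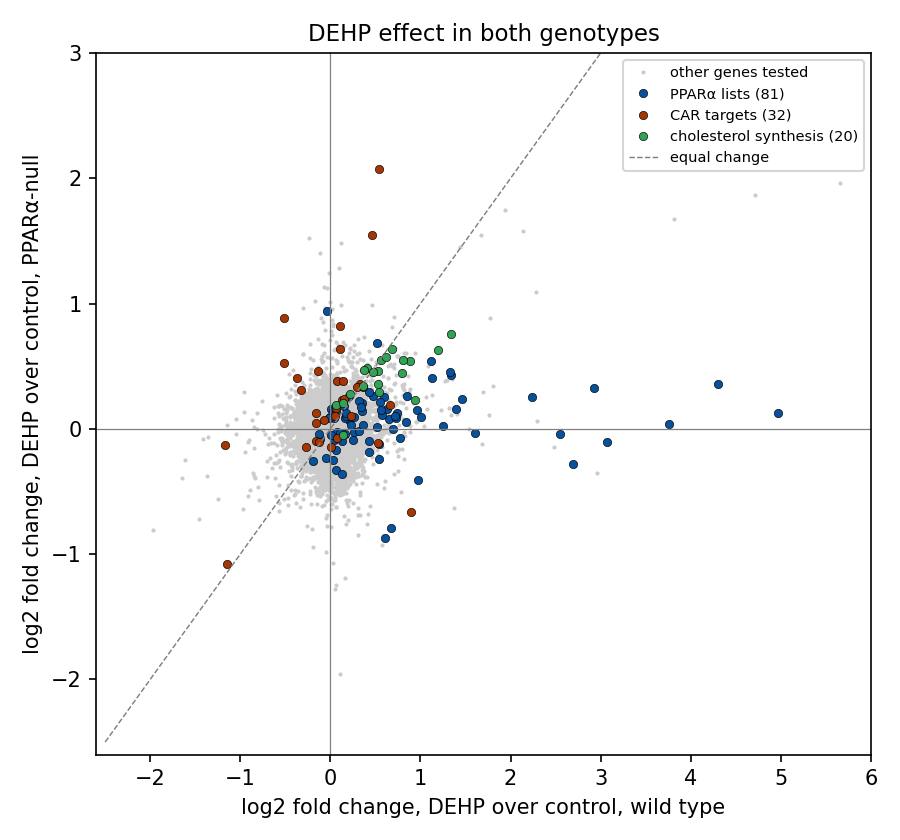
Log2 change with DEHP in wild-type mice (across) and in PPARα-null mice (up) for 81 PPARα target genes, 32 CAR targets and 20 cholesterol synthesis genes over all other genes (grey). The dashed line marks equal change.

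Without DEHP, the largest differences between null and wild-type livers were in ω-hydroxylases and in Serpinb1a and Mmp12 (n = 4 against 4). Cyp4a31 (-4.34 ± 0.36), Cyp4a10 (-3.43 ± 0.21, adjusted p = 2.77e-07) and Cyp4a14 (-3.29 ± 0.44) were lower in null mice. So were the lipid droplet protein Fitm1 (-2.52 ± 0.23), Vnn1 (-1.66 ± 0.27) and the peroxisomal reductase Decr2 (-1.57 ± 0.14). The protease inhibitor Serpinb1a was 9.06-fold higher in null mice (3.18 ± 0.19, adjusted p = 2.77e-07), the macrophage metalloelastase Mmp12 was higher by 2.73 ± 0.40 (adjusted p = 0.00128), the B cell adaptor Blnk by 1.57 ± 0.21 and Acot1 by 1.56 ± 0.27 (adjusted p = 0.00689). Cyp2b10 was lower in null controls (-1.23 ± 0.15, fold 0.427, adjusted p = 0.000269), and Ehhadh read -0.15 (adjusted p = 0.773).

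Between the control groups 237 genes differed, 128 higher and 109 lower in null mice, of which 43 differed at least 2-fold (19 higher, 24 lower). Groups did not overlap in 1540 genes (7.7%), where chance gives 2.86%, and in 235 of the 237. The highest number called by any other of the 35 splits was 1, so the real split was 1 of 35, the lowest share this test can give. The substrain of the mice differed between the genotypes, so every genotype difference here can equally be one of substrain.

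Of the 23 mitochondrial fatty acid oxidation genes 1 was higher and 9 lower in null controls, 3 and 12 when adjusted over the list alone (median -0.21, camera adjusted p = 1.37e-10, adjusted p = 0.232 with an estimated correlation). The carnitine carrier Slc25a20 (-1.30 ± 0.14), the carnitine palmitoyltransferase Cpt2 (-0.97 ± 0.11) and the acyl-CoA dehydrogenase Acadvl (-0.91) were lower, while Pdk4 was higher (1.02, adjusted p = 0.0433). Pdk4 lost its call in 6 of 8 leave-out fits, up to adjusted p = 0.135. Of 27 peroxisomal genes 0 were higher and 7 lower, 1 and 10 when adjusted over the list alone (median -0.22, adjusted p = 6.44e-12, adjusted p = 0.21 with an estimated correlation), among them Pxmp4, a peroxisomal membrane protein (-1.23 ± 0.08). Of 31 other PPARα targets 1 was higher and 7 lower, 3 and 15 when adjusted over the list alone (median -0.24, adjusted p = 2.23e-11, adjusted p = 0.21 with an estimated correlation). Of 32 CAR targets 2 were higher and 1 lower, 7 and 5 when adjusted over the list alone. Their median was -0.02, while the mean was 0.11 and camera pointed upward (adjusted p = 0.693), and without KO-117 the median was 0.005.

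Of 24 interferon-stimulated genes 6 were higher and 0 lower in null controls, 17 up when adjusted over the list alone (median 0.44, camera adjusted p = 1.68e-20, adjusted p = 0.21 with an estimated correlation). The interferon regulator Irf7 was higher by 1.22 ± 0.27, the ISG15 protease Usp18 by 1.14 ± 0.20 and the chemokine Cxcl10 by 0.89 ± 0.14. Irf7 lost its call in 6 of 8 leave-out fits, up to adjusted p = 0.109. Of 17 Kupffer cell and macrophage markers 2 were higher and 0 lower, 7 up when adjusted over the list alone (median 0.29, adjusted p = 8.61e-10, adjusted p = 0.232 with an estimated correlation). The lysozyme Lyz2 was higher by 0.93 ± 0.17 and the pore-forming protein Mpeg1 by 0.74 ± 0.13. Of 21 extracellular matrix and fibrosis genes 2 were higher and 0 lower, 14 up when adjusted over the list alone (median 0.27, adjusted p = 2.99e-13, adjusted p = 0.21 with an estimated correlation). These were the galectin Lgals3 (0.59 ± 0.11) and the collagen Col1a2 (0.78, adjusted p = 0.0474). Col1a2 lost its call in 7 of 8 leave-out fits, up to adjusted p = 0.142. No stellate cell marker of 16 was called, and 8 were higher when adjusted over the list alone (median 0.31, adjusted p = 2.38e-07, adjusted p = 0.21 with an estimated correlation). None of the 18 endothelial markers was called, and 0 when adjusted over the list alone (median 0.042, and 0.01 to 0.088 with KO-118 or WT-53 left out, adjusted p = 0.45).

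Of 13 hepatocyte genes of the central vein side 4 were higher and 1 lower in null controls, 5 and 1 when adjusted over the list alone (median 0.18, camera adjusted p = 0.000471, adjusted p = 0.228 with an estimated correlation). Among them were the aminotransferase Oat (0.77, adjusted p = 0.0167) and the glutamine synthetase Glul (0.38, adjusted p = 0.033), calls lost in 2 and 5 of 8 leave-out fits, up to adjusted p = 0.0633 and 0.102. Cholesterol synthesis had 1 higher and 0 lower gene, Hmgcs1 (0.68, adjusted p = 0.0276), and 1 when adjusted over the list alone (median 0.11, adjusted p = 0.00603, adjusted p = 0.652 with an estimated correlation). Leaving out 1 animal ended both calls, with adjusted p up to 0.0984 for Hmgcs1 and 0.246 for the list, and the list's median was 0.059 without WT-53 and 0.184 without WT-52.

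Under DEHP the largest differences between genotypes were in ω-hydroxylases (n = 3 null against 4 wild-type). Cyp4a31 (-8.28 ± 0.39), Cyp4a14 (-8.13 ± 0.48) and Cyp4a10 (-6.60 ± 0.23, adjusted p = 1.29e-10) were lower in null mice, and so were Vnn1 (-5.38 ± 0.29) and Ehhadh (-2.75 ± 0.17). Cyp2c37 was higher in null mice by 1.82 ± 0.15 (adjusted p = 1.09e-06), Cyp2c55 by 1.08 ± 0.17 (adjusted p = 0.000742). So were Meg3 (2.11 ± 0.20) and Slco1a4 (1.75). Cyp2b10, lower in null controls, read -0.14 (adjusted p = 0.699) under DEHP, and Hmgcs1 read 0.10 (adjusted p = 0.795).

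Under DEHP 2133 genes differed, 1014 higher and 1119 lower in null mice, of which 102 differed at least 2-fold (27 higher, 75 lower). Groups did not overlap in 4092 genes (20.5%), where chance gives 5.71%, and in 2044 of the 2133. The highest number called by any other of the 35 splits was 110, so the real split was 1 of 35, the lowest share this test can give. Without null DEHP animal KO-122 the count was 1019.

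Of the 27 peroxisomal genes 15 were lower and 0 higher in null mice under DEHP, 17 lower when adjusted over the list alone (median -0.48, camera adjusted p = 3.74e-20, adjusted p = 0.0861 with an estimated correlation), and without wild-type DEHP animal WT-58 the median was -0.31. Of 23 mitochondrial genes 17 were lower and 0 higher, 18 lower and 1 higher when adjusted over the list alone (median -0.68, adjusted p = 6.42e-23, adjusted p = 0.0861 with an estimated correlation). Of 31 other PPARα targets 19 were lower and 0 higher, 24 and 1 when adjusted over the list alone (median -0.67, adjusted p = 5.27e-28), with Fgf21 at -1.11 (adjusted p = 0.00132). Of 32 CAR targets 11 were higher and 0 lower, 14 and 5 when adjusted over the list alone (median 0.15, adjusted p = 0.000676, adjusted p = 0.114 with an estimated correlation), and without wild-type DEHP animal WT-59 the median was 0.1. Of 20 cholesterol synthesis genes 0 were higher and 2 lower, the same when adjusted over the list alone. Their median was 0.03, and -0.045 without WT-56, the mean -0.02 and camera's adjusted p = 0.735.

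Of 30 proteasome subunits 22 were lower and 0 higher in null mice under DEHP, 25 lower when adjusted over the list alone (median -0.33, camera adjusted p = 2.69e-19, adjusted p = 0.114 with an estimated correlation), with Psma7 at -0.69 ± 0.07. Of 36 oxidative phosphorylation genes 20 were lower and 0 higher, 23 lower when adjusted over the list alone (median -0.31, adjusted p = 1.06e-16, adjusted p = 0.126 with an estimated correlation), with the complex I subunit Ndufb3 at -0.77 ± 0.11. Higher in null mice were 21 of 32 complement and coagulation genes, with 0 lower, 27 and 1 when adjusted over the list alone (median 0.28, adjusted p = 3.74e-15, adjusted p = 0.0861 with an estimated correlation), among them C2 (0.73) and F5 (0.69). So were 11 of 18 endothelial markers, with 0 lower, 16 up when adjusted over the list alone (median 0.34, adjusted p = 2.11e-10, adjusted p = 0.0896 with an estimated correlation), among them Stab2 (0.49 ± 0.06) and the VEGF receptor Kdr (0.49). Of 24 interferon-stimulated genes 7 were higher and 0 lower, 11 up when adjusted over the list alone (median 0.42, adjusted p = 2.76e-06, adjusted p = 0.295 with an estimated correlation). Irf7 (1.22, adjusted p = 0.0126) lost its call only without null DEHP animal KO-122 (adjusted p = 0.0644). Stellate, macrophage and matrix lists were higher as well (5 of 16, 3 of 17 and 5 of 21 genes, 0 lower, medians 0.396, 0.324 and 0.265). Camera's adjusted p was 2.58e-06, 6.96e-05 and 6.96e-05, and 0.144, 0.336 and 0.321 with an estimated correlation. The T cell, B cell, neutrophil and bile duct lists were not called (camera adjusted p = 0.747, 0.551, 0.747 and 0.536).

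**Figure D3:**
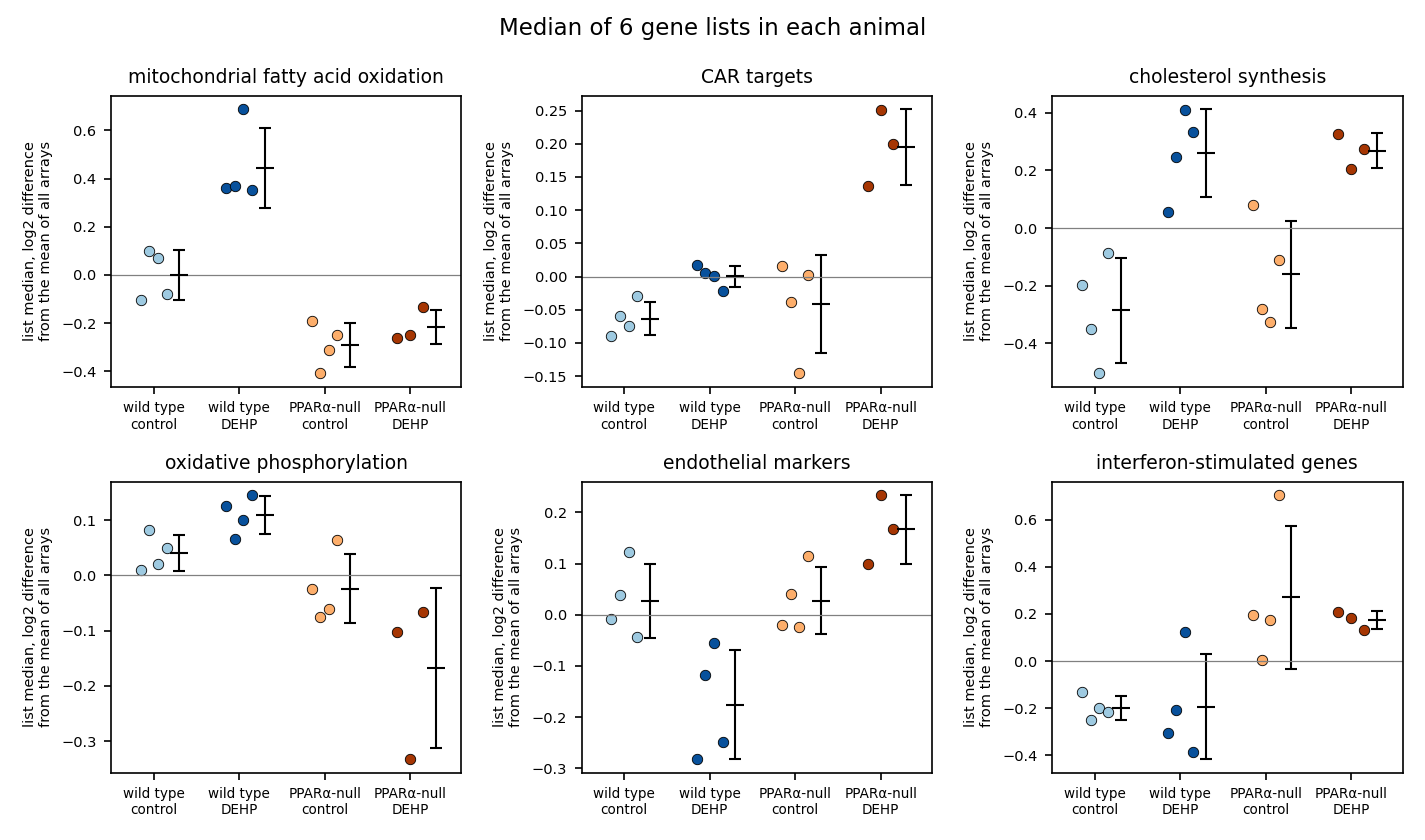
Median log2 difference of 6 gene lists from the mean of all arrays, in each animal of the 4 groups. Bars are group means ± SD (n = 4, 4, 4 and 3).

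The remaining lists fixed beforehand gave the following in wild-type mice given DEHP. Of 29 urea cycle and amino acid genes 1 rose and 5 fell, 1 and 8 when adjusted over the list alone (median -0.11, camera adjusted p = 0.000985, adjusted p = 0.367 with an estimated correlation). Without control WT-52 that median was -0.075. Of 18 heat shock genes 3 rose and 0 fell, 5 up when adjusted over the list alone (median 0.15, adjusted p = 6.27e-06, adjusted p = 0.204 with an estimated correlation). Of 19 p53 targets 3 rose, among them Gadd45b (0.66 ± 0.12), and 1 fell, 5 and 1 when adjusted over the list alone (median 0.05, adjusted p = 0.0258, adjusted p = 0.206 with an estimated correlation). Of 38 cell cycle genes 1 rose and 0 fell, 2 up when adjusted over the list alone (median 0.12, adjusted p = 2.98e-05, adjusted p = 0.301 with an estimated correlation). Of 36 oxidative phosphorylation genes 2 rose and 0 fell, the same when adjusted over the list alone (median 0.08, adjusted p = 0.000277, adjusted p = 0.464 with an estimated correlation), a call that ended when the arrays were quantile-normalized again (adjusted p = 0.415). Of 10 hepatocyte genes of the portal side 0 rose and 4 fell, 2 and 5 when adjusted over the list alone (median -0.26, adjusted p = 0.0352, adjusted p = 0.206 with an estimated correlation), a call that ended without DEHP animal WT-58 (adjusted p = 0.0753).

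Lists of other cell types and of carried-over tissue mostly stayed uncalled in wild-type mice given DEHP. Macrophage, T and natural killer cell, B and plasma cell, bile duct, exocrine pancreas and interferon lists had no gene called, and 0 when adjusted over the list alone (medians 0.07, -0.01, 0.01, 0.12, 0.05 and 0.07, camera adjusted p = 0.135, 0.865, 0.995, 0.0827, 0.224 and 0.239). Without DEHP animal WT-58 the macrophage and interferon medians were -0.04 and -0.044. Animal WT-57 read 0.302 for pancreas, 0.245 for bile duct and 0.305 for B cell markers, above the other DEHP animals, and without it the medians of these lists were -0.015, 0.013 and -0.111. Without animal WT-59 the T cell median was 0.026. The test pointed up for the T cell list and the mean of the B cell list was -0.03, against the sign of their medians. Of 15 neutrophil markers 1 rose, S100a8 (1.78 ± 0.24), also 1 when adjusted over the list alone (median 0.072, and 0.013 without DEHP animal WT-58, adjusted p = 0.165). Of 10 fat cell markers 2 rose, among them Fabp4 (1.68 ± 0.19), also 2 when adjusted over the list alone (median 0.05, adjusted p = 0.0142, adjusted p = 0.242 with an estimated correlation), and without DEHP animal WT-57 the call ended (adjusted p = 0.14, median 0.008). Of 16 stellate markers 0 rose and 2 fell, 0 and 3 when adjusted over the list alone (median -0.07, adjusted p = 0.0408, adjusted p = 0.464 with an estimated correlation), a call that also ended without animal WT-57 (adjusted p = 0.0789, median -0.034). None of 21 general hepatocyte genes was called, and 0 when adjusted over the list alone (median -0.10, adjusted p = 0.0492, adjusted p = 0.301 with an estimated correlation), which ended without control WT-53 (adjusted p = 0.124). Of 15 housekeeping genes 1 rose, Hprt (0.61 ± 0.07), 2 when adjusted over the list alone (median 0.028, and 0.002 without control WT-52, adjusted p = 0.111).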

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

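Of the tests below, those of a single null DEHP animal, of the share of hepatocytes and of a single null control were chosen only after the result was seen. So was the permutation test of the oxidative phosphorylation and proteasome medians. The tests of the other explanations were chosen before, although the drawing of splits for the interaction was changed after its first count.

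Oxidative phosphorylation and proteasome genes had a median change of -0.145 in null mice given DEHP (66 genes, 1 of them called). Null DEHP animal KO-122 alone might account for it, but without it the median was -0.105. A normalization error that follows brightness might do so too, yet 0 of 10000 random lists of matched brightness had a median that low (random median 0.064, central 95% from 0.024 to 0.109). A quality axis that also varies among the other arrays could be a source. Across all genes but these 66, its loadings correlated with the DEHP effect in null mice at r = 0.154 in absolute value, which left this undecided. The correlation does not show how the 66 genes themselves lie on that axis. The medians of single animals overlapped (exact two-sided permutation p = 0.114), and with so few animals this could not tell the pattern from the spread between animals. Of the null controls only KO-116 (-0.129) lay within the range of the DEHP animals. The median change was -0.204 without KO-116 and -0.11 without null control KO-118.

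Macrophage, interferon, matrix and stellate genes had a median difference of 0.354 in null over wild-type controls (78 genes). A lower share of hepatocytes might account for it. Endothelial markers, which would rise as well, read 0.042 in the controls, against 0.289 for macrophage markers. General hepatocyte genes read 0.035, with none called. Neutrophil markers were also higher by camera (median 0.111, adjusted p = 0.0154, 0.427 with an estimated correlation). Under DEHP, however, endothelial markers were higher in null mice by 0.344, about as much as macrophage markers (0.324). With DEHP the endothelial median had changed by -0.229 in wild-type and by 0.136 in null mice. General hepatocyte genes were under DEHP also higher in null mice, not lower (median 0.15, 5 of 21 called higher, 0 lower). Their camera adjusted p was 0.00894, and 0.219 with an estimated correlation. The difference of macrophage and endothelial markers was -0.065 or more in every null control and -0.118 or less in every wild-type control (exact permutation p = 0.0286, the lowest value these group sizes can give). Because this comparison was chosen after the result was seen, it cannot exclude the explanation. A single null control animal might carry it, but the lowest median without 1 of them was 0.277, reached without animal KO-115. By list the lowest was 0.353 for interferon genes without KO-118. Without KO-115 it was 0.238 for macrophage, 0.204 for matrix and 0.212 for stellate genes. Single animals stood out in some lists. The interferon median was 0.706 in KO-118 and 0.003 to 0.197 in the other null controls, and the stellate median 0.447 in KO-115 and 0.021 to 0.153 in the others. Substrain in place of genotype could produce it, and because 0 animals of the 2 genotypes share a substrain, this and genotype cannot be told apart.

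Genes that differed between control groups might mark strain variants in shared regions of the genome. The count covered the 162 of them that DEHP did not change in either genotype and that passed no interaction test. Pairs of neighbours by gene order in the supplied annotation were taken only where their symbols begin differently. There were 4, Btbd9 and Glo1, Unc13b and Atp8b5, Atp8b5 and Rusc2, and Tuba8 and Usp18. The mean in random sets was 1.12, and 2.4% of these sets had at least as many. Atp8b5 was counted with each of its neighbours, so the pairs are not all separate places. Unc13b (0.5) and Atp8b5 (-0.64) differed in opposite directions. The ratio of observed to random was 3.6, against 1.46 for the wild-type DEHP calls (37 pairs against 25.33), which is 2.45 times as high. The excess was marginal, and the variants themselves were not tested. Apart from Usp18 these genes were named only after their values were seen, and Usp18 is also an interferon-stimulated gene.

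The count of split labellings that called at least as many genes as the real labels, the real one included, was 1 of 35 for DEHP in wild-type mice, 1 of 35 for DEHP in null mice, 1 of 35 between controls, 1 of 35 between genotypes under DEHP, and 2 of 100 drawn for the interaction. The splits drawn for the interaction also broke up the DEHP effect within each genotype, so they cannot test the difference of effects alone.

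In 37 of the 504 groups of 4 animals looked at, the gap between 1 animal and the other 3 took up at least 0.83 of the group's range, in 31 genes and 6 lists, where chance alone gives about 1 in 20. The measure takes no account of distance, and some of these animals lay close to the others, as for Cyp1a1 (4.35 against 4.34) and Hprt (9.27 against 9.31). In wild-type DEHP animal WT-58 the log2 intensity was 12.56 for Cyp4a31, 11.12 for Vnn1, 10.73 for Acot2, 9.24 for Cyp2c37, 9.62 for Pklr, 7.47 for Rrs1, 6.32 for Usp18, 11.61 for Decr2, 11.38 for Slc25a20 and 10.34 for Cpt2, and the mitochondrial fatty acid oxidation list read 0.69. In null control KO-115 it was 8.86 for Nr1i2, 5.87 for Cyp4a10, 9.41 for Mt1, 9.07 for Urad, 6.58 for Fitm1 and 7.49 for Pecam1. In null control KO-116 it was 7.86 for Acot2, 9.46 for Ndufa2 and 10.07 for Acadvl, and the heat shock list read -0.11. In null control KO-118 it was 4.35 for Cyp1a1, 11.54 for Pygl and 5.15 for Cox6b2. In wild-type DEHP animal WT-56 it was 8.98 for Mvd and 7.44 for Saa3, in animal WT-59 it was 5.54 for Sap30 and 3.72 for Hao2, and in animal WT-57 the fat cell list read 0.15. In wild-type control WT-53 it was 10.79 for Lipa and 10.10 for Atp5e, in control WT-54 it was 11.23 for Arrdc3 with the p53 list at -0.08, and in control WT-55 it was 10.37 for Mfsd2a and 9.27 for Hprt, with the NRF2 list at -0.18 and the aryl hydrocarbon receptor list at -0.12.

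In 41 of the named genes the DEHP effect in wild-type mice minus that in null mice passed the interaction test. Among lipid genes and the pantetheinase Vnn1 the difference was 4.84 for Cyp4a14, 3.95 for Cyp4a31, 3.71 for Vnn1, 3.18 for Cyp4a10, 3.31 for Mogat1, 2.60 for Ehhadh, 2.97 for Acot1, 1.22 for Acaa1b, 0.81 for Ech1, 1.99 for Acot2, 0.91 for Eci1, 0.78 for Decr1, 2.59 for Cd36, 1.80 for Fabp4, 1.48 for Fabp2, 1.64 for Retsat, 0.61 for Acadvl, 1.23 for Pltp, -0.81 for Apoa4 and -0.72 for Acsm2. Among cytochromes it was -1.04 for Cyp2c54, -1.40 for Cyp2c37, -1.09 for Cyp2b10, -1.54 for Cyp2c55 and -0.63 for Cyp1a2. For the rest it was -1.13 for Pklr, -0.55 for Slc37a4, -0.53 for Pygl, -0.53 for Fcgr2b, -0.43 for Stab2, 0.61 for Psma7, 0.66 for Psma3, 0.79 for Rrs1, 0.93 for Snord22, 0.81 for Sap30, -0.76 for Urad, -0.74 for Gna14, -0.49 for F7, -0.46 for F5, 1.54 for Cox6b2 and 0.64 for Hprt. Leaving out 1 animal ended the calls of Acot2, Slc37a4, Fcgr2b, Rrs1, Sap30, Gna14 and F5 in 9, 10, 10, 12, 12, 12 and 13 of 15 fits, up to adjusted p = 0.0888, 0.077, 0.112, 0.0927, 0.109, 0.114 and 0.112. It ended those of Pltp, Cyp2b10, Stab2, Pklr and Acsm2 in 8, 7, 7, 6 and 2 fits, up to 0.0724, 0.0778, 0.0718, 0.0599 and 0.0575. It ended those of Ech1, Eci1, Cyp1a2, Snord22, F7 and Acadvl in 1 fit each, up to 0.0505, 0.0631, 0.0615, 0.0631, 0.0598 and 0.0509.

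In 17 lists camera called the same difference, and none of these calls held with an estimated correlation (lowest adjusted p = 0.135). The medians were 0.28 for peroxisomal genes, 0.387 for mitochondrial fatty acid oxidation, 0.414 for other PPARα targets, -0.114 for CAR targets, 0.059 for cholesterol synthesis, -0.193 for bile acids, -0.22 for glucose metabolism, -0.198 for urea and amino acids, -0.267 for complement and coagulation, 0.193 for heat shock, 0.266 for the proteasome, 0.101 for the cell cycle, -0.274 for male-biased and 0.106 for female-biased genes, 0.252 for oxidative phosphorylation, -0.28 for portal side genes and -0.365 for endothelial markers. The cholesterol call ended too, up to adjusted p = 0.242 without KO-115. The calls of the glucose, urea, cell cycle, male-biased, female-biased and portal lists ended when 1 animal was left out (adjusted p up to 0.144, 0.0618, 0.155, 0.267, 0.068 and 0.0893). The median was -0.217 for CAR targets without KO-121, -0.076 for glucose metabolism without KO-122, 0.031 for the cell cycle without KO-115, -0.161 for male-biased genes without WT-58 and 0.128 for heat shock without WT-58. It was 0.07 and 0.185 for female-biased genes without KO-116 and KO-115, and -0.427 for portal side genes without KO-122.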

How the results depend on the processing

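All alternatives were chosen before their results were seen, except the fits without 3 arrays (wild-type DEHP WT-58, null control KO-118, null DEHP KO-122), which were chosen after. No called gene named here and no list that stayed called turned its direction, but the median of the cholesterol list in the interaction was -0.019 without null control KO-115, and those of 8 (DEHP in wild-type mice) to 16 (DEHP in null mice) uncalled lists per contrast changed sign when 1 animal was left out. Against 770 genes for DEHP in wild-type mice, 182 moved at least 1.5-fold and 293 passed 0.01, and leaving out 1 animal gave 433 (control WT-53) to 614 (DEHP WT-57). Against 94 in null mice the count was 28 at 1.5-fold and 7 at 0.01 by construction, 32 after centring each array, 224 without the dimmest 25% of genes, 427 without the dimmer 50%, 1 with only these 2 groups fitted, 293 with a trended robust prior, 56 with array weights, 19 without the 3 arrays, and 9 (without DEHP KO-122) to 168 (without control KO-116), and the cause was not tested. Against 179 in the interaction it was 342 and 570 under the same filters, 424 with the robust prior, 95, 24, 66 without the 3 arrays, and 61 (without wild-type control WT-53) to 299 (without null control KO-116), and the cause was not tested. Between controls 1.2e+02 of 237 (to 2 significant digits) reached 1.5-fold and 114 passed 0.01, and under DEHP 410, 1003, 1331 with 2 groups fitted, 1104 without the 3 arrays, and 1019 (without null DEHP KO-122) to 1950 (without wild-type DEHP WT-58) against 2133. With an estimated correlation camera's adjusted p was 0.112, 0.0665 and 0.0792 for peroxisomal, mitochondrial and cholesterol lists in wild-type mice, 0.182 for cholesterol in null mice, and 0.178, 0.135, 0.135, 0.135 and 0.64 for peroxisomal, mitochondrial, other PPARα, CAR and cholesterol lists in the interaction, where cholesterol was also lost after quantile normalization (0.0796) and with fry (0.624) and ran from 0.000794 to 0.242 over left-out animals. Fry gave no call for 22 lists that camera called, among them urea (0.057), cell cycle (0.147), oxidative phosphorylation (0.185) and stellate lists (0.185) in wild-type mice, acute phase (0.0711), proteasome (0.11), oxidative phosphorylation (0.0803), matrix (0.454), endothelial (0.11) and B cell lists (0.426) in null mice, urea (0.105), cell cycle (0.442) and male-biased lists (0.368) in the interaction, and macrophage (0.0577) and cholesterol lists (0.49) between controls. The peroxisomal list in null mice ran from 0.0371 to 0.828. No paired analysis was possible because the replicate numbers are animal numbers and no number is shared between groups.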

Other observations

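The test of the female-biased list without the genes it shares with the PPARα lists was planned before its result was seen. In wild-type mice given DEHP 4 of 17 female-biased genes rose and 0 fell, 7 up when adjusted over the list alone (median 0.19, camera adjusted p = 9.54e-07). The list holds Cyp4a10, Cyp4a14 and 2 more genes that also stand in the PPARα lists. A response of those 4 genes alone might account for it. Without them 13 genes were left, 2 of them called (median 0.075, camera adjusted p = 0.0175), and with an estimated correlation the adjusted p was 0.206. The 2 called genes, Hao2 and Cyp3a44, lost their calls in 6 and 4 of 8 leave-out fits, up to adjusted p = 0.117 and 0.0652, so a rise beyond the shared genes is left open. Of 22 male-biased genes 4 rose and 3 fell, 4 and 8 when adjusted over the list alone (median -0.16, adjusted p = 0.165), among them Hsd3b5, a male-typical steroid dehydrogenase (-1.46), which lost its call in 7 of 8 leave-out fits, up to adjusted p = 0.0985.

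Of 19 lipoprotein genes 2 rose and 2 fell in wild-type mice given DEHP, 2 and 4 when adjusted over the list alone (median -0.07 with a mean of 0.004, camera adjusted p = 0.0611). The phospholipid transfer protein Pltp rose by 1.34 ± 0.17 and Apoa4 fell by 0.90 ± 0.06 on the log2 scale (adjusted p = 1.86e-07). The taurine-making enzyme Csad rose by 1.70 ± 0.23 (adjusted p = 0.000531), and the retinol saturase Retsat by 1.60 ± 0.19. Of 26 lysosome genes 4 rose and 0 fell, 6 and 1 when adjusted over the list alone (median 0.035, adjusted p = 0.111). Of 25 iron and heme genes 1 rose and 0 fell, 4 and 3 when adjusted over the list alone (median 0.08, adjusted p = 0.0664), and of 26 endoplasmic reticulum stress genes 2 rose and 2 fell, 2 and 8 when adjusted over the list alone (median -0.04, adjusted p = 0.165). Of 21 matrix genes 0 rose and 2 fell, the same when adjusted over the list alone (median -0.07, adjusted p = 0.165). Of 13 central vein side genes 1 rose and 1 fell, 2 and 2 when adjusted over the list alone (median 0.06, adjusted p = 0.392), and of 8 red cell markers 1 rose and 0 fell, 2 and 1 when adjusted over the list alone (median 0.07, adjusted p = 0.165). Of 19 clock genes 0 rose and 1 fell, the same when adjusted over the list alone (median -0.06, and -0.18 to 0.05 with WT-58 or WT-55 left out, with a mean of 0.01, adjusted p = 0.62). Without DEHP animal WT-58 the lysosome median was 0.006. With 1 animal left out the endoplasmic reticulum stress median reached -0.012, the central vein median 0.016, the red cell median 0.048 and the male-biased median -0.261.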
